A study of Mus musculus with 6 samples.

How the data were processed

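RNA labelled with 4-thiouridine (4sU) was measured in 6 libraries from mouse embryonic stem cells of the 129/Ola line in which, per the titles and treatment protocol in the labels, the zinc finger protein ZFP207 carries an auxin-inducible degron (AID). The degron is a short protein tag that lets the plant hormone indole-3-acetic acid (IAA) direct the tagged protein to the proteasome. Per the labels, 3 libraries came from cells without IAA (control) and 3 from cells kept with IAA for 5 h (depleted). The genotype label of the 3 controls reads WT and that of the 3 others names ZFP207 degradation. The controls were taken to be degron cells without IAA, and if they were untagged cells, every comparison would also be one between cell lines. 4sU is a uridine analogue that cells build into the RNA they make while it is present. Per the labels' protocols, the labelled RNA was biotinylated through its thiol groups, bound to streptavidin beads and made into libraries with a Vazyme kit. The values therefore weigh newly made RNA, precursors included, more than the whole RNA pool does. The length of the 4sU pulse, the strandedness of the kit and any spike-in are not given in the sources used here. No library of degron-free cells with IAA was analysed here, so IAA and the loss of ZFP207 enter every comparison together.

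The table as deposited holds estimated counts of reads per gene, given as whole numbers, for 55401 gene rows and 6 columns, each of which was matched by its name to a sample title. Per the submitters' processing notes, HISAT2 2.2.1, StringTie 2.2.1, DESeq2 1.42.0 and the mouse build mm10 were used, with no role stated for any of them. The row names join an Ensembl identifier and a symbol, the form that StringTie's export script writes when it turns coverage into counts, so the values were treated as estimated counts that were already whole. Such estimates can divide reads between overlapping genes or near-identical copies in ways the table does not show. Without a statement of strand, reads of a gene and of an antisense partner cannot be told apart, and overlapping genes are named beside those genes that the fixed choice below picked. They were not looked up for other genes given as examples. The table has 217 rows that share 107 symbols, which were kept as separate rows. No row lacked a symbol. Total counts were 25916628, 17631773 and 17613103 in control replicates 1 to 3 and 23110931, 23385133 and 14336811 in depleted replicates 1 to 3.

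Coordinates, genomic lengths and biotypes were taken from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, by symbol for 39082 rows and by synonym for 163, and 16156 rows found no match. Of the genes tested, 15362 (87.4%) had a genomic length. The table holds no exon structure, transcript length or GC content, so the planned comparison by intron content, the GC correction and the use of transcript length were not run.

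Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as its factor, which left 17573, and libraries were scaled by the trimmed mean of M values (TMM). The quasi-likelihood test with robust dispersions compared depleted with control over all 6 libraries, and Benjamini-Hochberg adjusted p-values under 0.05 were called. This fit had no block and is named the unpaired fit. Log2 fold changes are depleted over control, and levels are TMM-normalised CPM (counts scaled to a common library total), given as mean ± SD over 3 libraries. Fold values are those of the unpaired fit unless the paired one is named. The standard error is that implied by the fold change and its F statistic.

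The labels give both groups replicate numbers 1 to 3 without saying what a number stands for. Each library's deviation from its group mean in log2 CPM was therefore correlated across genes with those of the other group. The correlations were 0.214, 0.317 and 0.267 for the same number and between -0.23 and -0.024 for different numbers, so the numbers were taken to pair the libraries. Deviations cancel out within a group, so the negative values follow in part from the positive ones and are no separate evidence. The same edgeR test with the replicate number as a block, named the paired fit, is given beside each result whose call it changes or whose count it moves by more than 1.5 times. The series design speaks of independent replicates, and whether these were separate cultures is not given, so p-values measure the spread between these libraries.

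The 23 gene lists and the choice of genes to name were fixed before the data were examined. Lists were tested on voom values in limma 3.58.1 with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. As a description, the median of each list was also placed among 10000 random lists matched on genomic length and expression, each divided into 10 bins. The named genes are Zfp207. They also include, among called genes with a mean log2 CPM of at least 3, libraries that do not overlap between groups and a symbol that is no Gm, Rik, accession or pseudogene name, the 6 with the largest and the 6 with the smallest fold change. From each list, up to 2 called members with the smallest adjusted p were added. The same choice was applied to the paired fit after the data were seen, and other genes given as examples of a list are its members with their values.

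The relation with genomic length was measured by Spearman's correlation across genes, which are not independent replicates, and by the median log2 fold change of genes of at least 100 kb minus that of genes under 10 kb. The same difference of medians was taken per library from log2 CPM centred on each gene's mean and compared between groups by an exact two-sided permutation test. Alternatives were other scalings, other filters on low counts, DESeq2 1.42.0, other thresholds, protein-coding genes alone, other set tests, the replicate block, and the omission of each library in turn. Omitting each pair, the block in DESeq2, the block with a 2-fold minimum, the block with the other set tests and a correction for expression alone were added after the data were seen.

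On simulated counts with 200 changed genes among 17573, the unpaired fit recovered 0% of genes changed 1.5-fold, 11.9% of those changed 2-fold and 57.6% of those changed 4-fold, and none of its calls was an unchanged gene. The paired fit recovered 44.8%, 62.7% and 87.9%, and 9.1% of its calls were unchanged genes. A further list of 30 genes was shifted and also counted as changed. Pairing was built into these counts through their means and dispersions. The gain of the paired fit therefore does not bear on whether the numbers pair the real libraries. A simulated length difference of -0.328 was fitted as -0.323, and 0.003 was fitted where none had been put in. The noise was drawn independently between genes, and differences between replicate numbers were shared by both groups. A length difference between single libraries was therefore not simulated, and the 0.003 does not show how large a trend it could give. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and drawn with matplotlib 3.10.9.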

Results

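Newly made RNA was captured from mouse embryonic stem cells before and 5 h after the addition of IAA, which triggers the degradation of degron-tagged ZFP207, with controls taken as the same line from their titles although their genotype label reads WT. ZFP207, also called BuGZ, is a zinc finger protein known from spindle assembly and the kinetochore, and the series asks about its part in the function of U1 snRNP, the particle that recognises 5' splice sites. The 3 control and 3 depleted libraries held between 14336811 and 25916628 counts each. Mitochondrially encoded transcripts took 3.84 ± 0.667% of the counts in controls and 4.18 ± 1.52% in depleted libraries (mean ± SD, n = 3), and ribosomal protein genes took 1.47 ± 0.318% and 1.59 ± 0.330%. Both of these differences lay within the spread between replicates. The share of Malat1 was 0.36, 0.52 and 0.43% in control replicates 1 to 3 and 0.35, 0.38 and 0.35% in the depleted ones, and 23149, 21633 and 22936 genes had a count in controls against 22095, 21518 and 21395, so that both were lower in the depleted library of all 3 pairs. Log2 CPM correlated across genes at 0.911 to 0.946 between libraries of one group. On the first principal component, which held 31.4% of the variance, control replicate 2 stood at 104.25 and depleted replicate 2 at 38.49, while the other 4 libraries lay below 0. The libraries of replicate 2 thus shared part of their deviation on this component. The second component held 24.9% of the variance. On it controls stood at -53.01, -19.5 and -63.1 and depleted libraries at 17.98, 92.31 and 25.31.

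Zfp207 RNA itself (chromosome 11, 80383279 to 80408561, mm10) had a mean of 736 ± 329 CPM in controls and 919 ± 477 CPM after IAA. Its levels were 545, 1116 and 548 CPM in control replicates 1 to 3 and 695, 1467 and 596 CPM in the depleted ones, from 8804 to 32143 counts per library. The log2 fold change was 0.32 (SE 0.38, edgeR adjusted p = 0.823) in the unpaired fit and 0.29 (SE 0.07, edgeR adjusted p = 0.0196) in the paired fit, with a higher level in the depleted library of all 3 pairs. The paired fit did not call it without pair 1 (0.258) or pair 2 (0.237). The unpaired value was 0.752 without control replicate 2 and -0.188 without depleted replicate 2, with neither called. A degron acts on the protein, so these RNA levels do not check the depletion, and no protein was measured in these libraries.

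After 5 h of IAA, more genes were called lower than higher. These changes are relative to the other genes, because the scaling cannot show a change of all labelled RNA together. The unpaired edgeR fit called 137 genes lower and 2 higher among 17573. The median log2 fold change of the lower genes was -1.52, and 122 of them had fallen at least 2-fold. Dzip3, which encodes an E3 ubiquitin ligase, fell 7.37-fold, and the mitochondrial carbonyl reductase gene Cbr4 fell 5.77-fold. The genes that rose were Vamp2, a vesicle SNARE of regulated exocytosis, by 2.01-fold, and Cyp1a1, a xenobiotic-metabolising cytochrome P450, by 8.63-fold. In the paired fit, 1388 genes were lower and 871 higher, and the 139 genes of the unpaired fit were all among them with the same direction. Higher genes of the paired fit had changed little, with a median log2 fold change of 0.40 against -0.85 for lower ones, and 35 higher and 555 lower genes reached 2-fold.

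At an unadjusted p under 0.05 the unpaired fit held 1914 genes and the paired fit 4899. DESeq2 on the same genes without the block called 579 lower and 62 higher. No call survived the omission of any single library from the unpaired fit, apart from 1 gene when depleted replicate 1 was omitted, although the median log2 fold change of the 139 genes then stayed between -1.52 and -1.45. The paired fit kept 138 or 139 of the 139 when any pair was omitted.

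The 6 named genes that fell most each fell at least 4.91-fold. Dzip3 (chromosome 16, 48924228 to 48994142, overlapped by Gm22576) went from 94.8 ± 15.1 to 12.8 ± 5.04 CPM (log2 fold change -2.88, SE 0.30, edgeR adjusted p = 0.0300). Epdr1, which encodes an ependymin-related lysosomal protein (chromosome 13, 19591708 to 19619830), went from 14.02 ± 2.17 to 2.09 ± 1.09 CPM, a fall of 6.64-fold (edgeR adjusted p = 0.0316). Cbr4 (chromosome 8, 61487734 to 61503500) went from 15.3 ± 3.37 to 2.64 ± 0.512 CPM (edgeR adjusted p = 0.0300). Xpnpep3, a mitochondrial aminopeptidase gene (chromosome 15, 81400105 to 81457482), went from 52.1 ± 7.13 to 9.65 ± 4.98 CPM (edgeR adjusted p = 0.0357), and Dnajb7 and Gm17025 lie within the same interval. The zinc finger gene Zfp72 (chromosome 13, 74369321 to 74390861, overlapped by Gm8227) fell 4.98-fold to 5.09 ± 0.596 CPM (edgeR adjusted p = 0.0300). Zcchc24, a CCHC zinc finger gene (chromosome 14, 25711644 to 25769072), fell 4.91-fold to 3.42 ± 1.80 CPM (edgeR adjusted p = 0.0438).

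Vamp2 (chromosome 11, 69088528 to 69092381) rose from 51.3 ± 1.29 to 103 ± 7.06 CPM (log2 fold change 1.01, SE 0.14, edgeR adjusted p = 0.0300). By the same choice the paired fit placed 5 further genes ahead of it in paired log2 fold change, none of which passed the unpaired fit. They were the respiratory chain factor gene Higd2a (chromosome 13, 54590231 to 54591147), which went from 4.53 ± 0.907 to 12.3 ± 6.30 CPM, and the co-chaperone gene Dnajc25 (chromosome 4, 58994799 to 59025573), which went from 10.8 ± 1.29 to 23.3 ± 3.59 CPM. Fjx1 rose 2.2-fold, Rusc1 1.97-fold and Atp1b2, a sodium pump subunit gene, 1.96-fold in the unpaired fit. The paired log2 fold changes of the 5 genes ran from 1.34 for Higd2a to 1.010 for Atp1b2, against 1.007 for Vamp2. The adjusted p of these 5 genes in the paired edgeR fit lay between 0.00268 for Dnajc25 and 0.0316 for Rusc1.

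**Figure D1:**
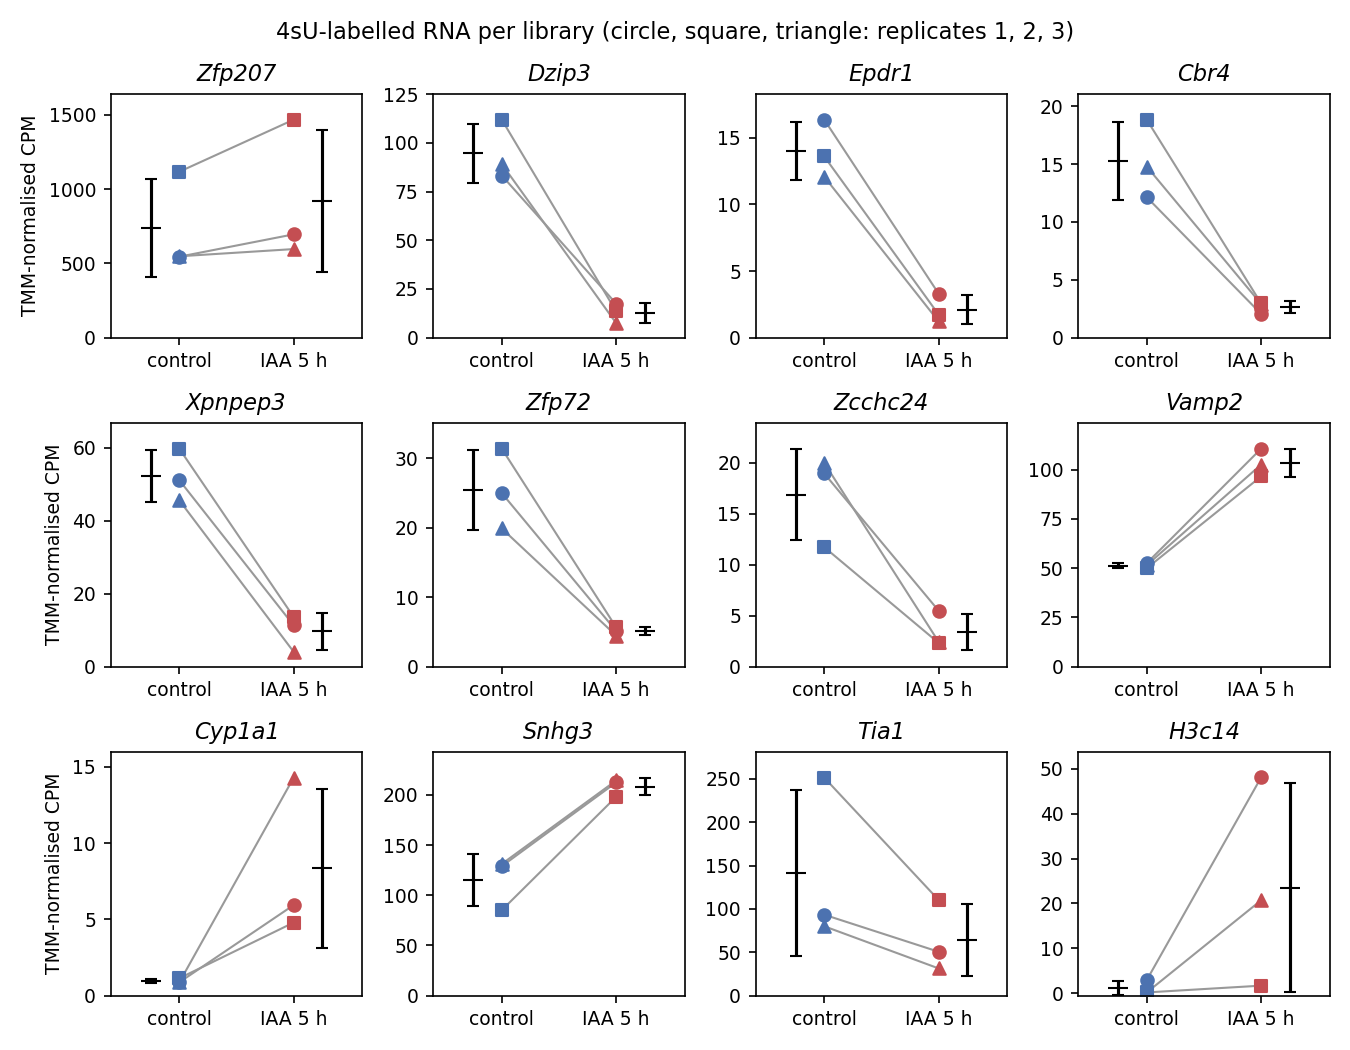
TMM-normalised CPM of 12 named genes in each of the 6 libraries, with controls on the left and cells with IAA for 5 h on the right of each panel, lines joining libraries of equal replicate number, and black bars giving the mean ± SD (n = 3). Dzip3 fell from 94.8 to 12.8 CPM and Vamp2 rose from 51.3 to 103 CPM with no overlap, while Zfp207 and Tia1 were highest in replicate 2 of both groups.

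Long genes lay lower than short genes after IAA. The comparison bears on U1 snRNP, which in textbook accounts also keeps long transcripts from ending early. The median log2 fold change was 0.139 for 5063 genes under 10 kb, 0.039 for 4673 genes of 10 to 30 kb, -0.069 for 3882 genes of 30 to 100 kb and -0.12 for 1744 genes of 100 kb or more. Over the 3 pairs the medians were 0.125 ± 0.033 for the shortest class and -0.122 ± 0.070 for the longest (mean ± SD), and the order of these classes was the same in each pair. In the paired fit, 122 of the genes under 10 kb (2.41%) were lower and 298 (5.89%) higher, while among genes of 100 kb or more 220 (12.6%) were lower and 23 (1.32%) higher. The class of 30 to 100 kb held 540 lower genes (13.9%) and 174 higher ones (4.48%), and the class of 10 to 30 kb held 433 (9.27%) and 341 (7.30%). From the shortest class to the longest, the unpaired fit called 10, 52, 60 and 9 genes lower and 1, 1, 0 and 0 higher. Its lower calls were thus fewest in the longest class, which also held the fewest genes. Of the 6 named genes that fell most, Dzip3 spans 69.9 kb, Xpnpep3 and Zcchc24 57.4 kb, Epdr1 28.1 kb, Zfp72 21.5 kb and Cbr4 15.8 kb. Vamp2, which rose, spans 3.9 kb.

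Across 15362 genes, Spearman's rho between log2 fold change and length was -0.237, and the long class lay 0.259 below the short one (difference -0.259). Per library, the long minus short difference was -0.081, 0.412 and 0.054 in control replicates 1 to 3 and -0.308, 0.212 and -0.308 in depleted ones. The groups differed by -0.263, against an SD of 0.255 in controls and 0.301 in depleted libraries (exact two-sided permutation p = 0.3, where 0.1 is the smallest possible). Within the pairs it was -0.228, -0.200 and -0.362, lower in 3 of 3 pairs (exact two-sided sign-flip permutation p = 0.25, the smallest that 3 pairs allow). The size of the trend rested on single libraries, since rho was -0.13 without control replicate 2, -0.143 without depleted replicate 1, -0.155 without depleted replicate 3 and -0.314 without depleted replicate 2. It was -0.124 with no filter on low counts.

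**Figure D2:**
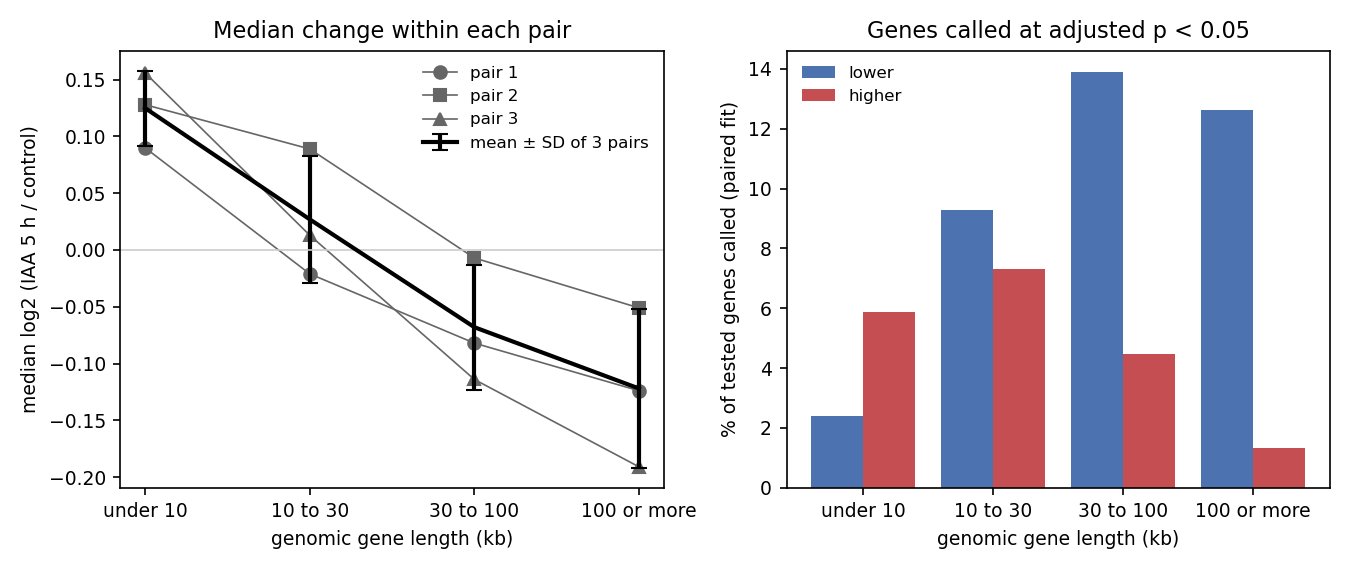
Left, median log2 fold change (IAA 5 h over control) of genes in 4 classes of genomic length in kb, for each of the 3 pairs (grey) and as mean ± SD over pairs (black). Right, percentage of the tested genes of each class called lower (blue) or higher (red) in the paired fit, where 2.41% of genes under 10 kb and 12.6% of genes of 100 kb or more were lower.

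Genes for RNA-processing proteins shifted little, and most of the shift was upward. Among the U1 snRNP proteins and U1-associated splicing factors, 3 of 16 tested genes changed in the paired fit. Tia1, a U-rich element binding protein that helps recruit U1, fell from 142 ± 95.3 to 64.1 ± 41.1 CPM (chromosome 6, 86404203 to 86433405; paired log2 fold change -1.13, SE 0.10, edgeR adjusted p = 4.58e-05). The U1 snRNP protein A gene Snrpa (chromosome 7, 27187006 to 27196271, overlapped by BC024978) rose 1.52-fold and the U1 snRNP component gene Snrnp70 went from 280 to 341 CPM. The list as a whole, with a median log2 fold change of 0.15, did not pass camera (adjusted p = 0.124). In the list of Sm proteins and the core spliceosome, 6 of 48 genes rose and 0 fell in the paired fit, among them Sf3b3 by 1.31-fold (overlapped by Cog4, Gm15895 and Snord111 among others) and Snrpe by 1.38-fold. The SR list held 8 that rose, such as Clk3 by 1.49-fold, Clk4 and Srsf5, and 1 that fell, the SR protein kinase gene Srpk2, by 1.84-fold (chromosome 5, 23503356 to 23684642, overlapped by Kmt2e). Of 23 hnRNP genes, 5 rose, Ptbp1 by 1.24-fold (overlapped by Plppr3, E130317F20Rik and Mir6910) among them, and Hnrnph2 fell 1.37-fold. Of 23 cleavage and polyadenylation genes, 3 fell, including Cstf3 by 1.7-fold and Pcf11 by 1.56-fold (overlapped by Gm26944), and 6 rose, including Cdk12 from 607 to 778 CPM.

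None of these genes was called in the unpaired fit, where 2 U1, 4 core, 4 SR, 1 hnRNP and 6 polyadenylation genes had an unadjusted p under 0.05 in edgeR, and DESeq2 called 1 core gene higher and 1 polyadenylation gene lower. Adjusted over the list alone, the unpaired counts stayed at 0, and the paired counts of higher and lower genes were 3 and 1 for U1, 8 and 1 for the core list, 9 and 1 for SR, 10 and 1 for hnRNP and 6 and 5 for polyadenylation factors. The core list (median 0.14, camera adjusted p = 3.12e-04), the SR list (0.22, adjusted p = 6.51e-04) and the hnRNP list (0.15, adjusted p = 0.00738) lay above other genes at the preset correlation, and each lost this with an estimated correlation (adjusted p = 0.464). Polyadenylation factors did not pass at either (adjusted p = 0.528 and 0.859). Against random lists of like length and expression, the core list stood at percentile 58.5, hnRNP at 48.6 and SR at 98.1. Without depleted replicate 2 the SR median was 0.088 and the hnRNP list was not called (median 0.117).

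Lists of several stress and growth responses lay higher at camera's preset correlation, with modest changes of single members. None of these calls held with an estimated correlation (adjusted p = 0.464 for each of the 5 lists). Of 26 immediate early genes, which respond within minutes to growth factors, 25 had a fold change above 0 and 6 rose in the paired fit, including Myc from 64.8 ± 10.5 to 91.4 ± 18.9 CPM (chromosome 15, 61985341 to 61990361) and Nr4a1 by 1.33-fold. Of 28 ATF4 and unfolded protein response genes, 7 rose and 0 fell, including the chaperone gene Pdia4 by 1.37-fold (with Mir704 in its interval), Sesn2 by 1.27-fold and Hspa5 from 359 to 427 CPM. Of 21 heat shock genes, 7 rose, including Hspb1 by 1.49-fold and Hspa1b from 7.80 to 16.9 CPM, and 2 fell. Of those, the HSP40 gene Dnajb4 (chromosome 3, 152181580 to 152210432, overlapped by Fubp1 and Gm40180) also passed the unpaired fit, at 35.3 ± 0.576 and 17.3 ± 1.80 CPM (edgeR adjusted p = 0.0438). Of 26 p53 targets, 6 rose, including Plk2 by 1.51-fold and the cell cycle inhibitor gene Cdkn1a by 1.38-fold, and 2 fell, the ribonucleotide reductase gene Rrm2b and Trp53cor1. Of 23 snoRNA host genes, 9 rose, including Snhg3 from 115 ± 25.97 to 208 ± 8.88 CPM (chromosome 4, 132351933 to 132353686, which holds Snora73a and Snora73b) and Gas5 by 1.39-fold (overlapped by Zbtb37 among others), and Nop58 fell.

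These lists passed camera at the preset correlation, with medians of 0.39 for immediate early genes (adjusted p = 3.12e-04), 0.24 for the ATF4 list (adjusted p = 0.00120), 0.22 for heat shock (adjusted p = 0.00572), 0.21 for p53 targets (adjusted p = 0.0248) and 0.32 for snoRNA hosts (adjusted p = 5.01e-05). Among matched random lists they stood at percentiles 99.99, 98.4, 95.2, 98.2 and 99.97. Adjusted over the list alone, the unpaired edgeR fit held 2 lower p53 targets, 1 lower heat shock gene, 1 higher snoRNA host and 0 of the others, and the paired fit held 11 higher and 0 lower immediate early genes, 8 and 0 of the ATF4 list, 12 and 2 heat shock genes, 11 and 2 p53 targets and 13 and 2 snoRNA hosts. The p53 list was not called without control replicate 2 (median 0.127), depleted replicate 1 (0.137) or depleted replicate 3 (0.175), and the median of immediate early genes was 0.183 without control replicate 2 and 0.221 without depleted replicate 1. The ATF4 median was 0.065 without control replicate 2 and 0.108 without depleted replicate 3.

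Of 8 tested targets of the aryl hydrocarbon receptor, a sensor of aromatic compounds, 3 rose. Cyp1a1 (chromosome 9, 57687928 to 57703824) went from 0.960 ± 0.154 to 8.34 ± 5.18 CPM (unpaired log2 fold change 3.11, SE 0.51, edgeR adjusted p = 0.0379). Cyp1b1 (chromosome 17, 79706940 to 79715061) went from 1.21 ± 0.303 to 3.91 ± 1.05 CPM (paired edgeR adjusted p = 0.0345) and Gstm1 from 9.38 to 14.8 CPM (paired edgeR adjusted p = 0.0478). Tiparp, Nfe2l2, Aldh3a1, Nqo1 and Ahrr were not called in either fit, and the last 2 had unpaired log2 fold changes of -0.11 and -0.36. The list had a median of 0.16 in the unpaired and 0.067 in the paired fit. It did not pass camera at the preset correlation (adjusted p = 0.0604 unpaired and 0.0841 paired) or at an estimated one (adjusted p = 0.464 unpaired). Adjusted over the list alone, 2 members were higher in the unpaired and 3 in the paired fit.

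Of 28 pluripotency genes, 5 were called in the paired fit, where 2259 of all 17573 genes were, and 0 in the unpaired fit. In the paired fit 4 rose, including Utf1 by 1.34-fold and Klf4 from 186 to 222 CPM, and Tdh, a threonine dehydrogenase gene of mouse stem cells, fell 1.55-fold (chromosome 14, 63492347 to 63509092, overlapped by Gm17232). Pou5f1 and Sox2 were called in neither fit. The list median was 0.10, with camera adjusted p = 0.0842 in the unpaired and 0.0191 in the paired fit, the latter lost with an estimated correlation (adjusted p = 0.462). Against random lists of like length and expression, whose median was 0.165, it stood low, at percentile 3.96. The upward call is thus relative to all genes and not to genes of like length and expression. Of 24 spindle checkpoint and kinetochore genes, Plk1 and Incenp rose and Zwilch and Ttk fell in the paired fit, Zwilch from 109 ± 33.7 to 62.9 ± 13.96 CPM (chromosome 9, 64137144 to 64173104, overlapped by Lctl), and the list did not pass (median 0.14, adjusted p = 0.184). Adjusted over the list alone, the paired fit held 6 higher and 1 lower pluripotency genes and 6 higher and 3 lower spindle genes, and the unpaired fit 0 of either list, with 1 gene of each at an unadjusted p under 0.05 and 0 in DESeq2.

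Markers of other cell types gave few calls. Map2, a neuronal microtubule protein gene (overlapped by Gm51629 and others), was lower in the paired fit (8.97 ± 3.87 and 3.47 ± 2.05 CPM) and was the only one of 15 ectoderm genes called. Hnf4a, a transcription factor gene of visceral endoderm (chromosome 2, 163506811 to 163572907, overlapped by Hnf4aos and Gm25881), was lower at 6.40 ± 3.01 and 0.8 ± 0.602 CPM (edgeR adjusted p = 0.0962 unpaired and 9.37e-04 paired), 1 of 16 primitive endoderm genes. The median of that list was 0.064 and its mean -0.031, so they differ in sign, with camera's direction up and fry's down. The imprinted placental gene Peg10 rose 1.37-fold in the paired fit, 1 of 15 trophectoderm genes. The 15 mesoderm and definitive endoderm genes, 10 feeder fibroblast markers and 17 genes of the 2-cell-like state gave 0 calls in either edgeR fit and 0 in DESeq2. At an unadjusted p under 0.05 these held 0 genes each in the unpaired fit and 2, 2 and 1 in the paired fit. Fibroblast markers had a median of -0.373, with -0.254, -0.626 and -0.057 in the 3 pairs. None of these 6 lists passed camera, with adjusted p from 0.237 for fibroblast markers through 0.350 for trophectoderm, 0.382 for mesoderm and 0.748 for the 2-cell-like state to 0.873 for primitive endoderm and 0.874 for ectoderm. Adjusted over the list alone, the unpaired fit held Hnf4a, and the paired fit Map2, 2 higher and 1 lower primitive endoderm genes and Peg10.

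The 89 cytoplasmic ribosomal protein genes lay slightly higher, with a fold change above 0 for 85. In the paired fit 7 rose and 0 fell, including Rpl27 by 1.37-fold and Rpl12 by 1.23-fold (with Snora65 inside it), and adjusted over the list alone 1 was higher. The median of 0.19 passed camera at the preset correlation (adjusted p = 5.01e-05) and was lost with an estimated one (adjusted p = 0.742), and it stood at percentile 32.6 of matched lists. Without control replicate 2 it was 0.029, and without depleted replicate 3 it was 0.067, neither of them called. Of 66 replication-dependent histone genes, 6 rose in the paired fit (5 adjusted over the list alone), including H2bc18 by 1.37-fold, but near-identical copies make single members uncertain. H3c14 went from 2.97, 0.228 and 0.217 CPM in the controls to 48.0, 1.73 and 20.7 CPM. The histone list passed camera only in the paired fit (adjusted p = 0.0797 unpaired and 2.10e-04 paired), and not there with an estimated correlation (adjusted p = 0.693). Its median stood at percentile 59.2 of matched lists. Of 23 genes in the list named small nuclear RNA genes, 1 copy of Rnu3b3 inside Tex14 was lower in the paired fit (5.60 ± 1.05 and 1.29 ± 1.54 CPM). Rnu3b3 is a U3 snoRNA gene, not a spliceosomal one. The list was picked by symbol and its pattern also takes Rn7sk, Rmrp, Rpph1, Rn7s and Rny names, so it does not stand for spliceosomal RNAs alone. Of 34 mitochondrially encoded genes none was called in either edgeR fit or in DESeq2. At an unadjusted p under 0.05, 0 mitochondrial genes stood in the unpaired and 2 in the paired fit. The small nuclear RNA and mitochondrial lists did not pass camera (adjusted p = 0.725 and 0.718). The former had a median of 0.016 but a downward direction in the test. Adjusted over the list alone, the paired fit held 1 gene of the small nuclear RNA list and the unpaired fit 0 in these 4 lists.

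**Figure D3:**
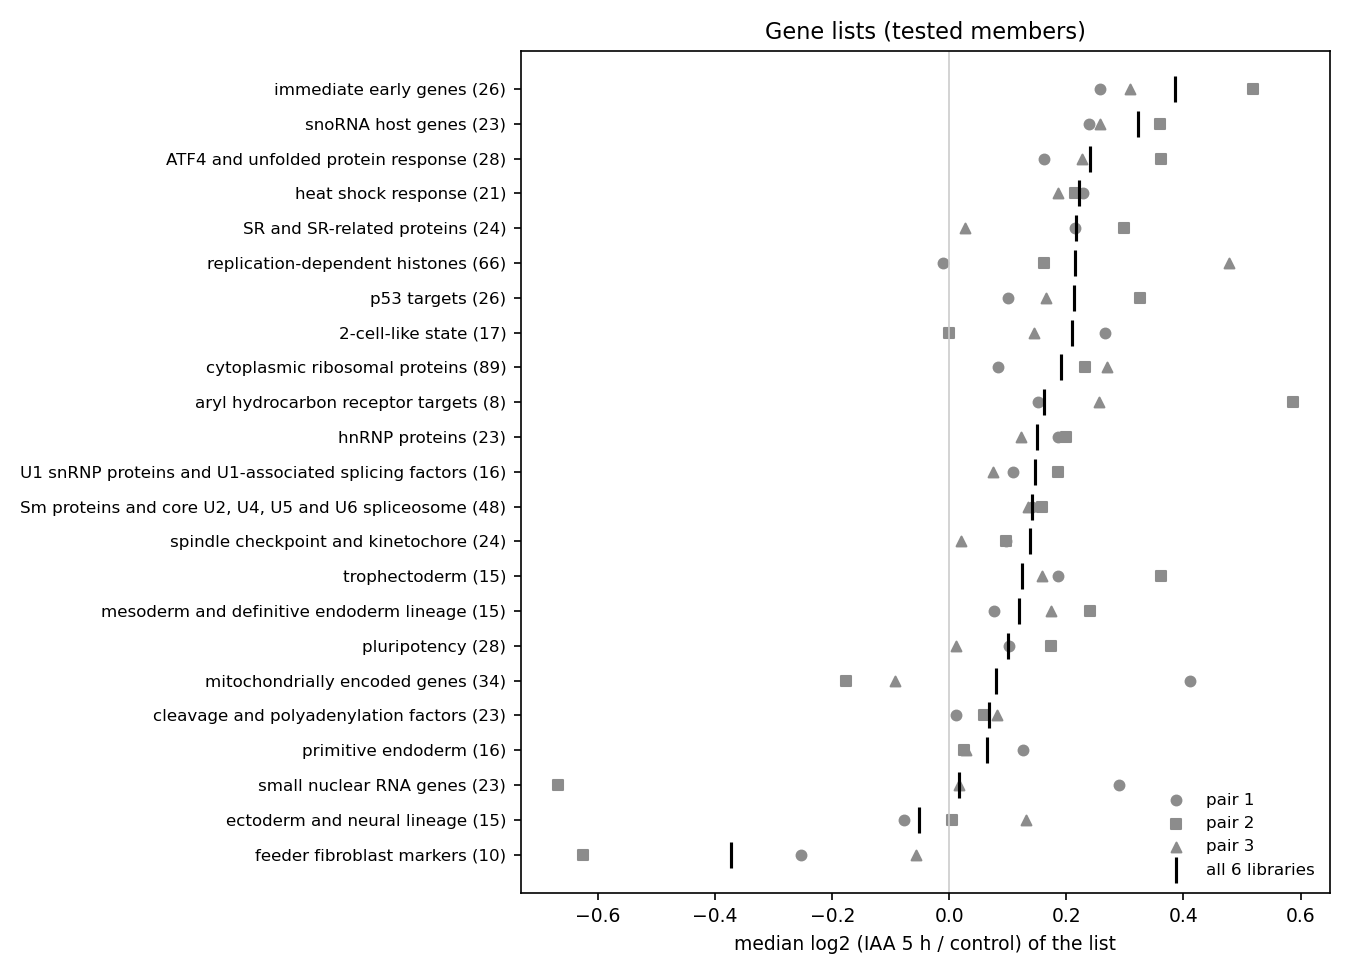
Median log2 fold change (IAA 5 h over control) of the tested members of the 23 gene lists, with member numbers in parentheses, for each of the 3 pairs (symbols) and for all 6 libraries (bars). Immediate early genes had the highest median of all 6 libraries at 0.385, and feeder fibroblast markers the lowest at -0.373, where the pairs ranged from -0.626 to -0.057.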

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

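The omission of each pair, the block in DESeq2, the block with a 2-fold minimum and the block with other set tests were chosen after the data were seen. All 139 genes called by the unpaired edgeR fit kept their direction under each scaling, filter, tool and omission tried. Between 126 and 139 of them stayed called under the other scalings and filters (126 with relative log expression factors), and 139 in both DESeq2 runs and with the replicate block. The unpaired fit gave 0 to 1 higher and 0 to 1 lower genes when any library was left out, at 1477 to 2380 genes with an unadjusted p under 0.05, and DESeq2 was not run there. Fewer libraries leave fewer degrees of freedom by construction. Higher and lower counts were 62 and 579 in DESeq2 on the same genes, 41 and 527 in DESeq2 with its independent filtering, 0 and 0 at an adjusted p under 0.01 in edgeR, and 871 and 1388 with the replicate block. Among protein-coding genes alone 4 were higher. With the replicate block they were 35 and 555 at 2-fold or more, 491 and 927 without pair 1, 412 and 1016 without pair 2, 250 and 699 without pair 3, and 1137 and 1401 in DESeq2. The change of Zfp207 passed the threshold with the replicate block (0.29), with the block in DESeq2 (0.306) and with the block without pair 3 (0.358), and not without pair 1 (0.258) or pair 2 (0.237) nor in any setting without the block. In the unpaired fit with one library left out it ranged from -0.188 (without depleted replicate 2) to 0.752 (without control replicate 2). Spearman's rho with length stayed negative throughout, at -0.124 with no filter, -0.127 in DESeq2 with independent filtering, -0.315 in protein-coding genes with a log2 CPM of at least 3, and -0.314 to -0.13 with one library left out, where long minus short ranged from -0.413 (without depleted replicate 2) to -0.13 (without control replicate 2). The cause was not tested. Of the 9 lists called with camera's preset correlation, 0 were called with an estimated correlation, with fry, or with either in the paired fit, and the cause was not tested. Their medians were then 0.142 for the core spliceosome, 0.216 for SR, 0.149 for hnRNP, 0.213 for p53, 0.385 for immediate early, 0.24 for ATF4, 0.221 for heat shock, 0.322 for snoRNA host and 0.19 for ribosomal protein genes, and in the paired fit 0.134, 0.209, 0.147, 0.233, 0.429, 0.254, 0.212, 0.267 and 0.197. With one library left out the p53 median ranged from 0.127 to 0.276, ribosomal proteins from 0.029 to 0.347 and hnRNP from 0.109 to 0.19, with calls lost as given above. The 2-cell-like list turned to -0.313 without control replicate 2, mitochondrial genes to -0.214 without depleted replicate 1 and small nuclear RNA genes to 0.483 without depleted replicate 2, each then past the threshold. The first and last of these lists also passed the other way, at 0.688 without depleted replicate 2 and -0.47 without depleted replicate 1. Over single omissions the 3 medians ranged from -0.895 to 1.576, -0.214 to 0.238 and -0.47 to 0.483. The cause was not tested. Pairing by replicate number changed no other list call than those of pluripotency and histone genes. Scaling moved the median of all genes between -0.037 and 0.039. Each scaling sets the libraries to a common total or typical gene, so a median near 0 follows largely by construction. With no spike-in known, a change of all labelled RNA together would not show. The analyses by intron content, GC content and transcript length were not run. On simulated counts with pairing built in, recovery of 1.5-fold changes was 0% unpaired and 44.8% paired. Of the calls there, 0% of the unpaired and 9.1% of the paired ones were unchanged genes. The latter share exceeds the adjusted p threshold of 0.05. The effect of depth was not simulated.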

Other observations

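The list of repair genes and that of Zfp genes were written after the most changed genes had been seen, and the tests of the replicate numbers, of the compound and, apart from the paired count of genes, of the splits that part all 3 pairs were chosen after their results were seen.

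Genes of double-strand break repair and the Fanconi anaemia pathway were among those that fell. Of 89 tested, 12 were lower in the unpaired edgeR fit, and 25 were lower and 2 higher in the paired fit. The checkpoint kinase gene Atr went from 131 to 39.3 CPM, Rad50 of the break-binding MRN complex from 84.0 to 23.2 CPM, and the Holliday junction resolvase gene Gen1 from 62.7 to 14.9 CPM. The end-joining gene Xrcc5, the BRCA2 partner gene Palb2 and the shieldin gene Shld2 fell with log2 fold changes of -1.12, -1.15 and -1.62, and Fanca and Fanci with -0.84 and -1.02. Atm, Brca2 and Prkdc were lower in the paired fit only, with log2 fold changes of -0.40, -0.55 and -0.53. Shld3 and Slx1b were the members called higher, in the paired fit only. Of the 89 members, 59 had an unpaired log2 fold change below 0.

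Because 8 of the members had been seen beforehand, the other 81 were tested alone, and 5 of them were lower in the unpaired fit, against 12 of the full list. Their median was -0.10, with -0.079, -0.097 and -0.153 in the 3 pairs, and 17 were lower and 2 higher in the paired fit (camera p = 0.00203, with an estimated correlation p = 0.0492, and p = 0.107 with an estimated correlation in the paired fit). Genomic length and expression, as matched here, do not account for the lower median, which stood at percentile 0.12 of random lists matched on both. Genes of those lists were drawn independently. The percentile thus ignores correlation among repair genes and does not measure the spread between libraries. Splits of the 6 libraries are too few for a share under 0.05, and 2 of the 10, the real one included, gave a median as far from 0 (0.1 in the real split, 0.129 in the highest other, which set control replicate 1 and depleted replicates 1 and 3 against the rest and so parted 1 pair). Among the 4 that part all 3 pairs, where the others swap the groups of 1 pair, 1 of 4 reached the real value, and the highest other gave 0.068. The cause was not tested, and an effect of the compound remains as open as one of the protein.

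Genes named Zfp, several of which were among the most changed, did not fall as a class. Of 354, 7 were lower in the unpaired fit, and 48 were lower and 31 higher in the paired fit, with a median of 0.03, at percentile 10.6 of random lists matched on length and expression. Of the 347 not seen beforehand, 2 were lower in the unpaired fit, and 42 were lower and 30 higher in the paired fit. Their median was 0.049, at percentile 38.0. Among all 17573 genes, 137 were lower in the unpaired fit, and 1388 were lower and 871 higher in the paired fit.

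The lower level of long genes was weighed against expression level and grouping. Given mean expression, the partial correlation with length was -0.232 in the mean of the 3 pairs (SD 0.055), against -0.184 (SD 0.064) without this correction. In the unpaired fit of all 6 libraries it was -0.299, against -0.237. Mean expression alone therefore does not account for the lower level of long genes. Within pairs long minus short was -0.263 (SD 0.087) and negative in 3 of 3. Each replicate number occurs once in each group, so this mean equals the group difference by design and as a test decides nothing on replicate numbers. By the same design, a difference between numbers that both groups share cancels from the group difference and cannot give it. A difference that the groups do not share is part of the spread between libraries and stays open. With splits too few for a share under 0.05, 3 of the 10 gave a rho as far from 0 (0.237 in size in the real one, 0.358 in the highest other, which put both replicate 2 libraries on one side). Among the 4 that part all 3 pairs, 1 of 4 reached the real value, and the highest other gave 0.203. Those libraries had the highest long minus short value of their groups, 0.412 and 0.212. Early transcript ending or slower elongation could also give lower long genes and was not tested, since the table has no positions within genes.

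The rise of single aryl hydrocarbon receptor targets may come from indole-3-acetic acid itself or from the loss of ZFP207. The list as a whole did not pass camera in either fit, so no rise of the class is claimed. In the paired fit 3 of 8 members were higher, Cyp1a1, Cyp1b1 and Gstm1, and these explanations cannot be told apart because every depleted library also had the compound. Degron-free cells with IAA would separate them.

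Splits of the libraries also bear on the counts, and they are too few for a share under 0.05. The real split gave 139 calls in the unpaired fit and the highest other 1, so 1 of 10 reached the real count. Among the 4 splits that part all 3 pairs, the real one alone (1 of 4) called genes, 139 against 0 in the highest other in the unpaired fit and 2259 against 0 in the paired fit, where the others swap the groups of 1 pair. For gene lists at camera's preset correlation, 6 of the 10 splits called as many as the real 9, up to 11, and 2 of the 4 that part all 3 pairs did, with 9 in the highest other, so such calls also arose where both sides mixed control and depleted libraries.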
